A study of Mus musculus with 2 samples.

How the data were processed

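Gene expression was measured in bone marrow mononuclear cells of C57BL/6 mice on 2 one-colour arrays, 1 from an untreated culture and 1 from a culture given the herbal drug ninjin'yoeito (NYT). Per the labels, the cells were flushed from the femurs of mice aged 2 to 4 months in medium with 2% fetal bovine serum and collected at day 11. Both arrays lay on 1 slide, so slide does not separate them. The groups were taken from the treatment stated in the labels. The labels and the series' design text name different RNA extraction kits, so the kit is not settled here. Dose, and whether the cells of both cultures came from the same animals, are not given in the sources used here.

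Spot intensity values were deposited by the authors as scanner output, extracted with Agilent Feature Extraction 10.7.1.1 per the file headers, whereas the submitters' processing notes name version 9.5.1.1. Per the file headers, the processed intensity was detrended spatially and multiplicatively, and spots near background held surrogate values. The headers list the background correction setting as off. No scaling between the arrays had been applied to it. The spot flags deposited by the authors mark outliers, saturation and signal well above background. A value table deposited by the authors for the same arrays was also an intensity on a linear scale. Its sorted values were equal within a relative difference of 1e-06 for 39073 of 39429 probes, so it had been quantile normalized between the arrays, and its median was 72.1 in both columns. Each column followed its own array's scanner values in rank (Spearman 0.99996 for control and 0.999996 for NYT across probes, against 0.935 when crossed). It was not centred, its direction followed its columns, and how it was made beyond that is not given in the sources used here.

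Each array held 43020 spots other than controls, for 39429 probes, of which 399 were printed 10 times. Outlier flags removed 258 spots on the control array and 165 on the NYT array, and 8 probes had no spot left on both. No spot was saturated. Processed intensities were averaged over the spots of a probe on the log2 scale, and each array's 75th percentile was subtracted. A gene was represented by its brightest probe well above background on both arrays. A probe was called well above background when more than 50% of its spots were. A gene with no probe well above background on 1 array was given a bound, the bright value against the higher of the dim array's lowest signal well above background and the dim probe's own.

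Probes were named through a table of RefSeq genes for assembly GRCm38.p6, used for names only. An accession named 26761 probes, a current symbol 3814 and a synonym 639, and 8215 kept the name in the files. Probe coordinates are those of the file headers, on the mouse build mm9.

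With 1 array per group there was no test, no p-value and no spread between replicates. Genes were counted by size, at a 2-fold difference. The spread of the probes printed 10 times gave the only error, which covers spot noise on an array and neither cultures nor hybridisations. Its median SD was 0.031 on the log2 scale on the control array, 0.041 on the NYT array and 0.046 for the difference between them (247 probes). The number of arrays, 1 per group, limits the precision. The 42 gene lists, the rule for named genes, the thresholds and 30 alternatives were fixed before the data were examined. For each list with at least 5 measured members, the median log2 difference was given with an exact binomial (order statistic) 95% interval over its member genes. Its percentile among 10000 random lists of equal size, matched on mean expression in 20 bins, describes these 2 arrays only.

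Named genes were the 10 with the largest difference in each direction among the brighter genes whose other measured probes had the same sign, leaving out clone names, predicted genes and accessions. The 5 genes in each direction with the highest bound among those detected on 1 array were added. From each list, up to 4 measured members with the largest difference were named, with members detected on 1 array at a bound of at least 2-fold. Some genes that the rule took are not reported here.

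The alternatives were quantile normalization, scaling to the median of probes detected on both arrays, no scaling, loess between the arrays, normexp background correction with an offset of 50, the authors' value table, no filter on dim probes, the brighter genes alone, the mean over probes of a gene, a 3-fold threshold and another detection flag. Scaling to the E1A spike-in spots was added after seeing the data. The counting step was tested on simulated arrays of the NYT against control comparison with 16996 genes. It called 0 of 67 genes changed 1.5-fold, 67 of 67 changed 3-fold, 66 of 66 changed 6-fold and 0 of 16796 unchanged genes. Every simulated probe had the same small noise, and the simulated cultures did not differ otherwise. The absence of false calls was thus fixed by the setting and gives no false positive rate for the real counts. The list interval held the true median in 96.6% of simulated lists of 15 members. R 4.3.3 with limma 3.58.1 read and scaled the arrays, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest.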

Results

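Bone marrow mononuclear cells, a mixture of blood-forming and immune cells, were cultured with or without NYT, a herbal drug, and their RNA was hybridised to whole-genome mouse arrays at day 11. The design implies 1 comparison, which asks how gene expression in the culture given NYT differed from that in the untreated culture. Each group had 1 array, so every value below is a difference between 2 arrays with no replicate check, and p-values were not computed. Probes well above background numbered 24506 (62.2%) on the control array and 22753 (57.7%) on the NYT array. The NYT array was dimmer before scaling, with a 75th percentile intensity of 728 against 1476, a ratio of 2.03. Differences are log2 intensity, NYT minus control, after scaling each array to that percentile, and the median SD of a difference from spot noise was 0.046.

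The array of the NYT culture showed lower signal for the marker genes of most blood lineages, with medians nearer to 0 for macrophages (-0.26) and B cells (-0.30), which still lay in the lowest 2.5% of matched random lists. Marker genes of mast cells and basophils, eosinophils, megakaryocytes and mature neutrophils had median log2 differences of -3.82, -3.82, -3.78 and -3.44, each below all 10000 random lists matched on brightness. Dio2, which activates thyroid hormone, and Cdkn1c, an inhibitor of the cell cycle, were 166-fold and 108-fold higher on the NYT array. Mcpt8, a basophil protease, and Ccl5, a chemokine of T cells and other leukocytes, were 98.7-fold and 72.8-fold lower. Genes of the lysosome, and of a list joining the unfolded protein response with amino acid stress, had median differences of 0.87 and 0.84. Without scaling these turned to -0.15 and -0.18.

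Of 30165 named genes, 16996 were measured on both arrays. Among these 1908 (11.2%) were at least 2-fold higher and 1868 (11.0%) at least 2-fold lower on the NYT array. The split was 1870 higher against 1826 lower with quantile normalization and 1955 against 1841 with median scaling. It was 211 against 6190 without scaling, 950 against 2359 after loess, and 166 against 7485 when scaled to spike-in RNA, a setting added after seeing the data. At 3-fold, with the scaling kept, 507 were higher and 1167 lower. The median difference of all measured genes was 0.29 as scaled, -0.73 without scaling, -0.02 after loess and -0.89 with spike-in scaling, and the list medians below are best read against these shifts. Across genes, which are not independent replicates, the arrays correlated at r = 0.935. Where a gene had several measured probes (4048 genes), 1061 had probes of opposite sign, and among those at least 2-fold apart 93 of 720 did.

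**Figure D1:**
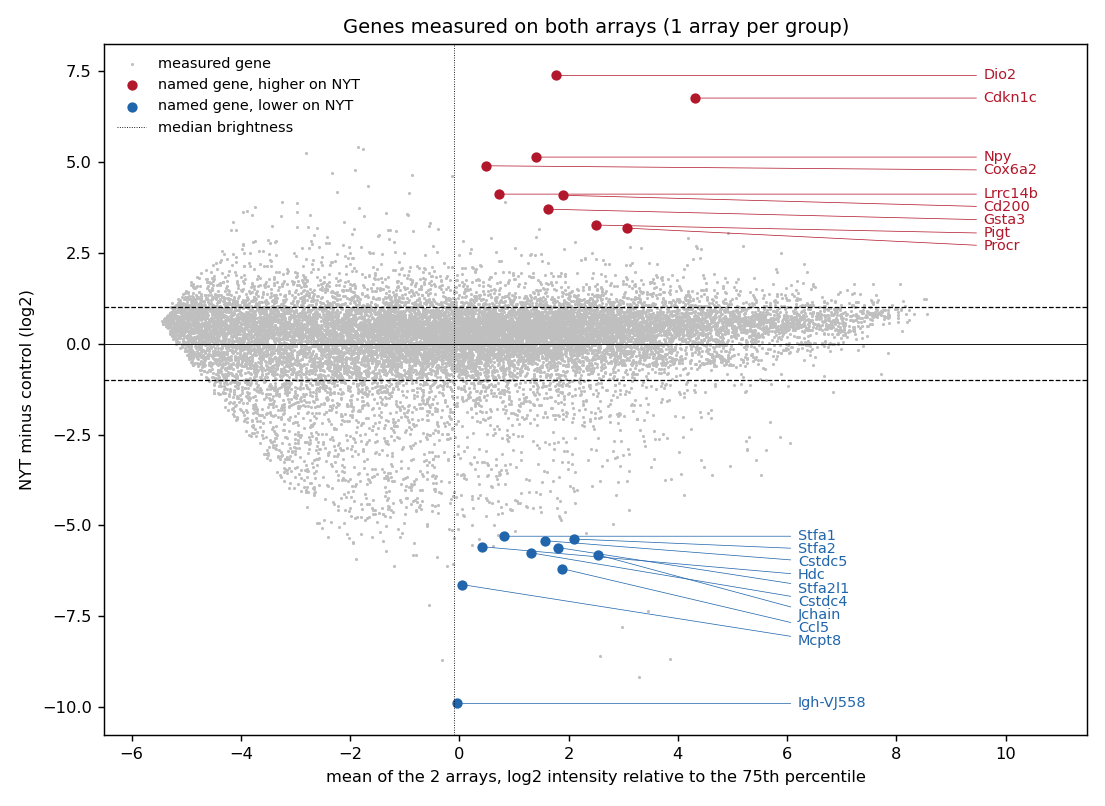
Log2 difference, NYT minus control, against the mean log2 intensity of the 2 arrays, for 16996 genes, with the brighter named genes of largest difference coloured and dashed lines at 2-fold. Dio2 lies 7.38 above 0 and Igh-VJ558 at -9.89, and the cloud of genes has a median of 0.29, which is -0.73 without scaling.

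The named genes higher on the NYT array had varied known functions. Npy, a neuropeptide, was 35.1-fold higher, Cox6a2, a subunit of cytochrome c oxidase found mainly in muscle, 29.7-fold, and Lrrc14b 17.3-fold. Cd200, a surface glycoprotein that restrains myeloid cells, was 16.9-fold higher and Gsta3, a glutathione transferase, differed by 3.70 on the log2 scale. Procr, the protein C receptor, which marks stem cells in bone marrow, was 9.04-fold higher. Pigt differed by 3.26 on that scale by its brightest probe, but by only 0.25 by its other probe. The probe for Dio2 lies on chromosome 12 at 91963235 to 91963294, minus strand (mm9). That for Cdkn1c lies on chromosome 7 at 150644753 to 150644812, minus strand (mm9).

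Among the lower genes, Jchain, which joins secreted immunoglobulins, was 55.9-fold lower and Hdc, which makes histamine, 48.0-fold. The cysteine protease inhibitors Cstdc4, Stfa2l1, Cstdc5, Stfa2 and Stfa1 were 53.9-fold, 48.8-fold, 42.7-fold, 41.4-fold and 39.3-fold lower. These are near-identical copies on chromosome 16, so their separate values are uncertain. Igh-VJ558, an immunoglobulin heavy chain variable family with many copies, was 950-fold lower by 1 probe and -4.21 on the log2 scale by another, with cross-hybridisation left open. With normexp background correction Mcpt8 and Igh-VJ558 differed by -5.70 and -7.94, against -6.63 and -9.89. The probe for Mcpt8 lies on chromosome 14, starting at 56702300, minus strand (mm9).

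Signal well above background on 1 array alone was found for 1855 genes on the control and 553 on NYT, of which 731 and 293 had a bound of at least 2-fold. With the other detection flag the numbers were 1507 and 1539, so the difference in number did not hold. Fcer1a, the high-affinity IgE receptor, was at least 108-fold lower on the NYT array, Klrd1, a natural killer cell receptor, at least 103-fold, and Il18r1 at least 81.1-fold. The chemokines Ccl8 and Xcl1 were at least 69.8-fold and 56.7-fold lower. In the other direction Arfgef3, Boll, Vash2, Pcdhac2 and Pcdhb1 were at least 30.3-fold, 18.8-fold, 17.2-fold, 15.4-fold and 14.2-fold higher on the NYT array.

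Granulocyte and megakaryocyte markers were lower on the NYT array. Of 15 measured mast cell and basophil genes, 14 were at least 2-fold lower, and 7 more were detected on the control alone. With normexp background correction the mast cell and megakaryocyte medians were -2.93 and -3.17. Over the brighter members the mast cell, eosinophil and megakaryocyte medians were -4.50, -4.52 and -3.15. Cpa3, a mast cell protease, differed by -7.18 and Gata2, a transcription factor of mast cells and progenitors, by -5.18. Of 11 eosinophil genes, 10 were lower, including Epx, eosinophil peroxidase (-5.10), and Ear1 (-4.63), whose family has near-identical copies. Of 21 megakaryocyte and platelet genes, 17 were lower, with Selp, P-selectin, at -4.68 and Itga2b, an integrin of platelets, at -4.65. Of 24 late neutrophil genes, 22 were lower, with Cxcr2, a chemokine receptor, at -4.99. The early neutrophil granule list had a median of -2.38 (11 of 12 lower), with Cebpe at -3.25 and Mpo, myeloperoxidase, at -3.06.

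T and NK cell genes had a median of -2.74 over 15 measured members (95% interval -4.60 to -0.76), of which 11 were lower and 1, Il7r, was higher. The median was -0.92 over the 6 brighter members and -4.23 over 30 members with no filter on dim probes. The 15 remaining members were detected on the control array alone, including Gzmb, a cytotoxic protease (at least 48.9-fold), and Cd8b1 (at least 18.0-fold). Il2rb differed by -5.42 and Cd3d, part of the T cell receptor complex, by -4.93. The B and plasma cell list had a median of -0.30 (interval -0.71 to 0.01), with 17 of 21 members under 2-fold. Its brightest member on the control array, Jchain, differed by -5.80, and Igh-VJ558, outside the list, by -9.89. Vpreb3 differed by -4.34, Ebf1 by -1.05 and Cr2 by -1.02, and Igll1 was at least 11.2-fold lower.

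Stem and progenitor genes had a median of -2.41 (15 of 21 lower), including Angpt1 (-4.05) and Slamf1 (-3.96, or -2.55 with normexp background correction). Procr, also in this list, was higher (3.18), and the median was -1.07 over the 8 brighter members. Erythroid genes had a median of -2.07 (8 of 14 lower, interval -3.86 to 0.42), with Aqp1 at -4.73 and Gata1 at -3.86. The brightest erythroid member, Hemgn, stood at 0.02 and Slc4a1, a dim gene, at 1.30. The erythroid median was 0.07 without the filter on dim probes. The 11 heme synthesis genes were all under 2-fold, with a median of 0.23 as scaled and -0.79 without scaling. Stromal genes had a median of -2.58 (17 of 23 lower), with the collagens Col1a1 and Col1a2 at -5.33 and -4.39. Fstl1, Vim and Lepr of this list were higher, at 1.64, 1.49 and 1.36. Endothelial genes had a median of -1.09 (7 of 12 lower), where Stab2 stood at -3.57 and Vwf at -3.17 by 1 probe and -0.48 by another.

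**Figure D2:**
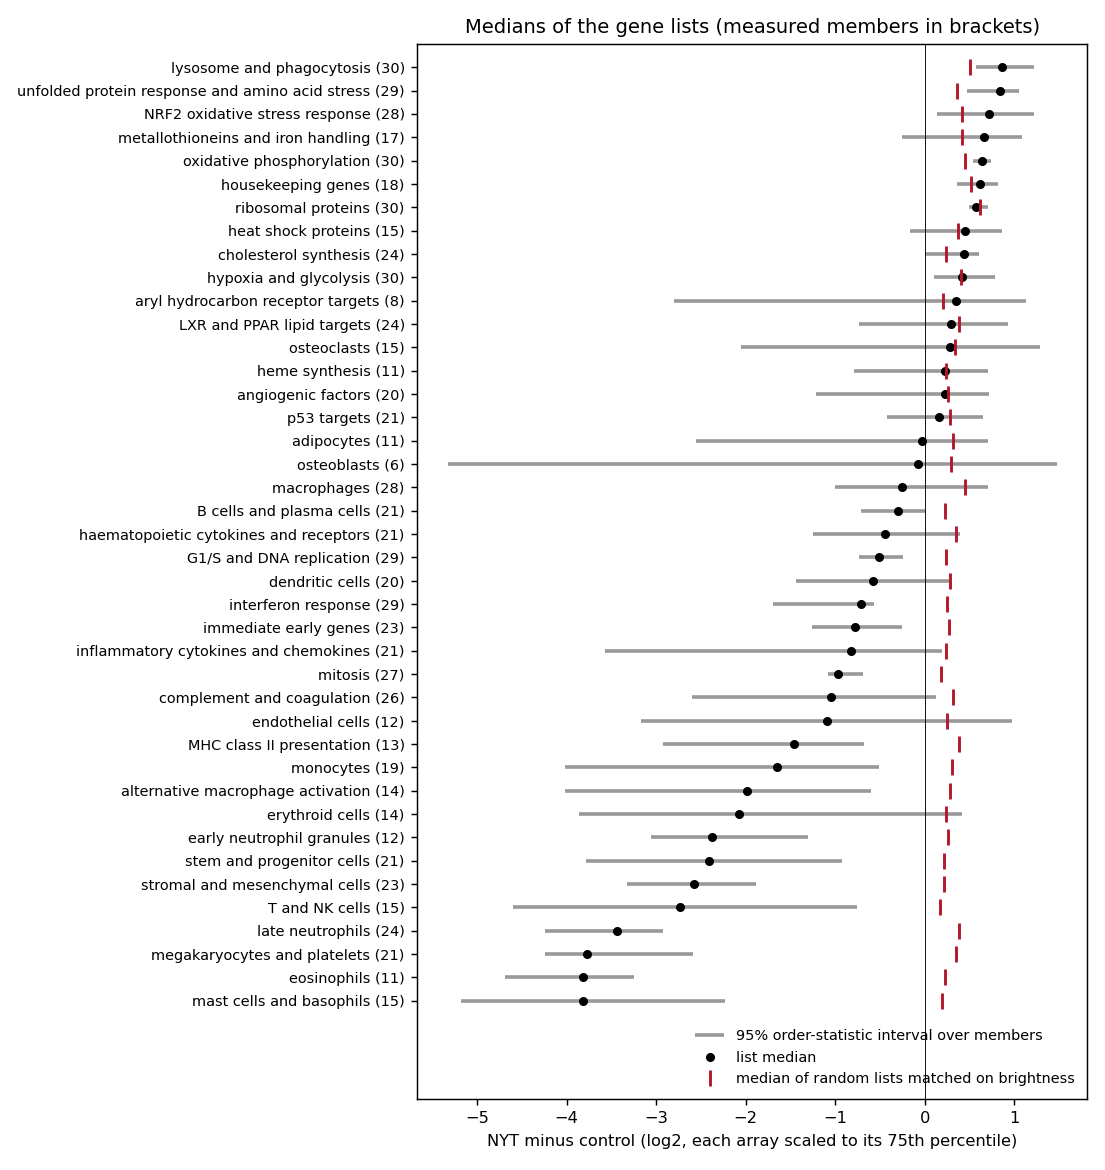
Median log2 difference, NYT minus control, of 41 gene lists (black points) with the 95% order statistic interval over member genes (grey bars) and the median of random lists matched on brightness (red ticks). Mast cell, eosinophil, megakaryocyte and late neutrophil lists lie at -3.82 to -3.44. The lysosome list and the list of unfolded protein response and amino acid stress lie at 0.87 and 0.84, which turn to -0.15 and -0.18 without scaling.

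Macrophage genes went both ways, with 8 of 28 higher, 10 lower and a median of -0.26. The complement genes C1qa, C1qb and C1qc, made by tissue macrophages, differed by -5.21, -3.74 and -3.58. Siglec1, an adhesion receptor, differed by -2.69 by its brightest probe and 1.28 by another. Chosen after their values were seen, Trem2 (1.63), Gpnmb (1.65), Cd68 (1.18) and Ctsk (2.29) were higher. Monocyte genes had a median of -1.65 (10 of 19 lower), with Ccr2 at -4.33 and Fn1, fibronectin, at -4.14. Alternative macrophage activation genes had a median of -1.99 (11 of 14 lower), with Folr2 at -4.84 and Stab1 at -4.03, and Arg1 was at least 3.67-fold lower. Dendritic cell genes had a median of -0.58 (8 of 20 lower), with Cd7 at -4.24 and Itgax at -2.15.

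The MHC class II list had a median of -1.46 (8 of 13 lower), with H2-Aa at -3.82, H2-Eb1 at -3.21 and Cd74, the invariant chain, at -2.92, while Ctss, a cathepsin of antigen processing, stood at 0.64. Inflammatory cytokine genes had a median of -0.83 (9 of 21 lower), with Il1b at -6.12, Cxcl2 at -4.55 and Cxcl10 at -4.07. Interferon response genes had a median of -0.72 (12 of 29 lower), with Gbp2 at -3.24 and Ifi44 at -2.94. Complement and coagulation genes had a median of -1.05 (13 of 26 lower, 5 higher), or -0.43 over the brighter members, with F5, a clotting factor, at -4.22. Immediate early genes had a median of -0.78 (10 of 23 lower), with Egr1 at -2.88. Haematopoietic cytokine and receptor genes had a median of -0.44 (7 of 21 lower, 1 higher), with Epor at -3.39 and Kit at -3.33.

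The mitosis list had a median of -0.97, with 13 of 27 members at least 2-fold lower and none higher, including Ccnb2 (-1.59), Cenpa (-1.47) and Top2a (-1.34). The G1/S and DNA replication list had a median of -0.51, with 2 of 29 members lower, Pole (-1.46) and Mcm5 (-1.46), and 1 higher, Cdt1 (1.15).

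Lysosomal genes had a median of 0.87 as scaled (12 of 30 higher, 1 lower), higher than 99.99% of matched random lists, but -0.15 without scaling and -0.31 with spike-in scaling. Among them the proton pump subunits Atp6v1h and Atp6v1a differed by 1.68 and 1.41 and Ctsz, a cathepsin, by 1.42, while Mcoln1 stood at 1.51 by 1 probe and 0.24 by another. The list called unfolded protein response here also holds amino acid stress genes, and these were not separated. Its genes had a median of 0.84 (10 of 29 higher, 2 lower), but -0.18 without scaling and -0.34 with spike-in scaling. Trib3 (2.92), Asns, which makes asparagine (1.94), and Slc3a2 (1.82) led them, while Vldlr stood at -2.84. Oxidative stress genes had a median of 0.72 (11 of 28 higher, 2 lower), but 0.24 with quantile normalization, -0.30 without scaling and -0.46 with spike-in scaling. The glutathione transferases Gstm3 and Gstm1 differed by 2.80 and 2.67 and Srxn1 by 1.77, whereas Gsta1 was at least 25.6-fold lower on the NYT array. Glutathione transferases have similar copies, so their separate values are uncertain.

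**Figure D3:**
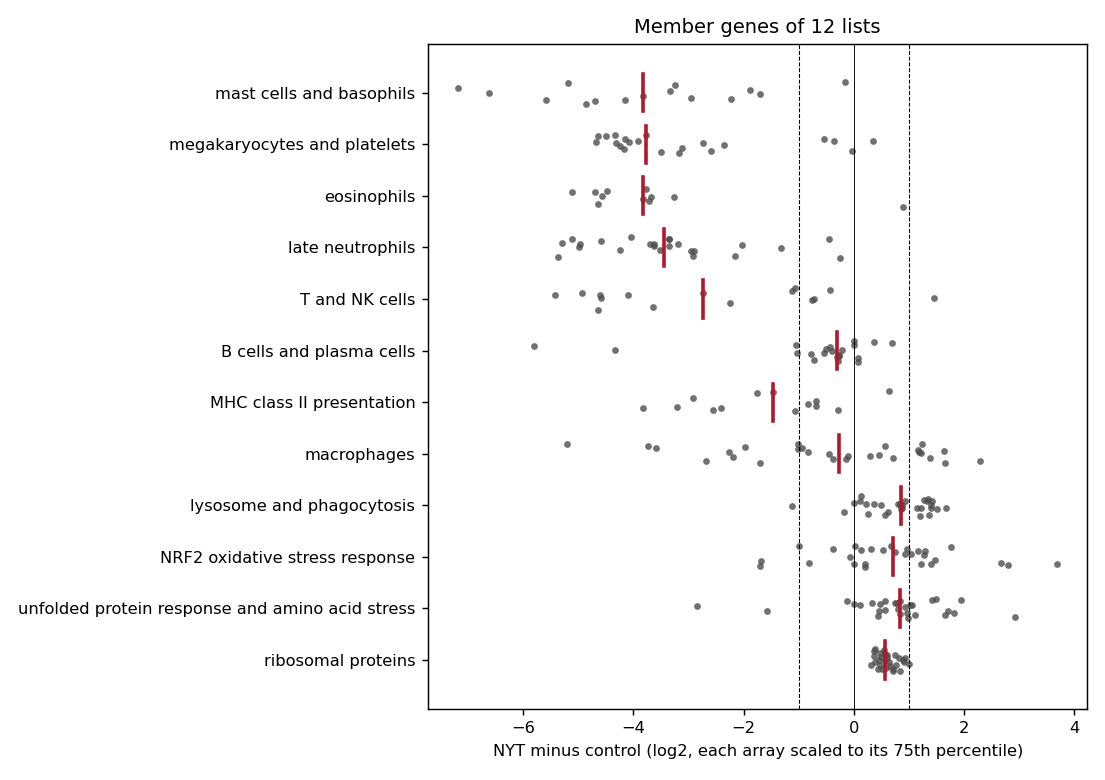
Log2 difference, NYT minus control, of each measured member (points) of 12 gene lists, with the list median (red bar) and dashed lines at 2-fold. Members of the macrophage list lie on both sides of 0, from -5.21 for C1qa to 2.29 for Ctsk, and the ribosomal list, at 0.57, turns to -0.45 without scaling.

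Metabolic and housekeeping lists lay above 0 as scaled and below 0 without scaling. Oxidative phosphorylation had a median of 0.64 (2 of 30 higher, Sdhc at 1.09 and Ndufa1 at 1.01) and -0.38 without scaling. Ribosomal proteins had a median of 0.57 and housekeeping genes 0.62, and without scaling these were -0.45 and -0.40. Hypoxia and glycolysis genes had a median of 0.42 and cholesterol synthesis genes 0.44, against -0.60 and -0.58 without scaling. In these lists P4ha2 differed by 2.53 and Pfkfb4 by -1.44, and Insig1 by 1.46.

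Intervals of the macrophage, erythroid, B cell, endothelial, dendritic cell, inflammatory, complement, and haematopoietic cytokine medians included 0. These medians were nonetheless among the 23 of 41 in the lowest 2.5% of matched random lists, with 3 in the top 2.5%. The lists that follow had intervals that included 0 and lay in neither tail. Metallothionein and iron handling genes had a median of 0.66 (6 of 17 higher, 4 lower), with Hp at -2.91 and Lcn2 at -2.90. Heat shock genes had a median of 0.45, with Hspb8 at -3.79 (-1.86 with normexp) and Hspe1 at 1.12. Aryl hydrocarbon receptor targets had a median of 0.36 over 8 genes, with Cyp1b1 at -2.11, Cyp1a1 at least 3.59-fold higher, and Aldh3a1 at 1.13 by its brightest probe but -1.62 by another. Lipid targets of LXR and PPAR had a median of 0.29, with Apoc1 at -2.95. Osteoclast genes had a median of 0.29 (6 of 15 higher, 4 lower), with Ctsk at 2.29 and Mmp9 at -4.58. Angiogenic factors had a median of 0.22, with Vegfc at -3.18 (-1.67 with normexp). The p53 targets had a median of 0.16, with Plk2 at 2.91 and Btg2 at -2.57. Adipocyte and osteoblast genes had medians of -0.03 and -0.08, with Dgat2 at -2.96 and Spp1 at 1.48. Of these lists, those above 0 as scaled lay below 0 without scaling. The Y-linked genes Eif2s3y, Uty and Ddx3y differed by -0.20, -0.08 and 0.18, Kdm5d was not well above background on either array, and Xist, detected on the control array alone, has no fold because its bound was under 1.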

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

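A signal outside the main measurement differed between the arrays. Of the 10 E1A spike-in RNAs, 8 were well above background on both arrays. Before scaling, 1 of these, E1A_r60_a107, was 2.25 higher on the NYT array on the log2 scale (4.75-fold, from 6.32 to 8.57, over 32 spots), while the other 7 lay between -0.12 and 0.24. The slope of the spike-in curve in the file headers was 0.942 for control and 0.831 for NYT, and the scanner software marked the second as out of range. No explanation was tested for this spike-in.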

How the results depend on the processing

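Scaling to spike-in RNA was chosen after seeing the data; the other settings were planned. No paired analysis was possible because each group had 1 array and no value came from a test, and for the same reason no array could be left out in turn. The cause was not tested for any change below, except that fewer or more genes entered with another filter or threshold. Genes at least 2-fold higher and lower numbered 211 and 6190 without scaling, 4755 and 3414 with no filter on dim probes, 865 and 626 among the brighter genes, 507 and 1167 at 3-fold, and 166 and 7485 with spike-in scaling. After loess 950 were higher. With the other detection flag, genes detected only on the NYT array numbered 1539 against 1507 only on the control, so the larger control number was lost.

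The 9 higher and 10 lower genes with the largest differences that the text names stayed at least 2-fold apart in the same direction under the planned scaling, background, filter and probe settings that gave a value, the nearest to 0 being 1.76 for Pigt and -4.93 for Stfa1. For these genes that was largely fixed in advance, since they were chosen for their large differences and removing the scaling moves each value by 1.02. Of the 23 lists in the lowest 2.5% of matched random lists, 22 stayed below 0 under the same planned settings. The other, erythroid genes, reached 0.07 with no filter on dim probes. No list stayed above 0 throughout. The setting without scaling fixes this, since it lowers each value by 1.02 and the highest list median was 0.87. Over 41 lists, 327 values stayed within the interval of the main value, 31 moved outside it and 9 were counted as reversed. Some medians whose interval included 0 also changed sign and count as moved or as staying within it. With normexp, 41 of 163 single genes moved by over 1.5 times, all nearer to 0 and all but Runx2 (-0.65 to 0.15) keeping their sign, and those named in the report were Igh-VJ558 (-7.94), Mcpt8 (-5.70), Cpa3 (-5.76), Il1b (-5.22), Il2rb (-4.16), Col1a1 (-4.26), Gata2 (-3.82), Epx (-4.04), Cd3d (-3.95), Folr2 (-3.48), Aqp1 (-3.68), Selp (-3.56), Cxcl2 (-3.25), Vpreb3 (-3.08), Ccr2 (-3.61), Cd7 (-3.49), Cxcl10 (-3.48), Angpt1 (-3.15), Slamf1 (-2.55), Hspb8 (-1.86), Vegfc (-1.67), Apoc1 (-2.14), Ifi44 (-1.95) and Siglec1 (-1.93). Among the brighter genes the T and NK median was -0.92 (-4.23 with no filter) and the medians of stem and progenitor (-1.07), erythroid (-2.70), mast cell (-4.50), eosinophil (-4.52), megakaryocyte (-3.15), complement (-0.43) and osteoclast (0.91) genes also moved by over 1.5 times. So did mast cell (-2.93) and megakaryocyte (-3.17) medians with normexp, and eosinophil (-4.48) and osteoblast (0.59) medians with no filter. Oxidative stress stood at 0.24 with quantile normalization and with the value table. The osteoblast and aryl hydrocarbon receptor lists had too few brighter genes for a value there.

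Without scaling, medians whose interval excluded 0 reversed for oxidative stress (-0.30), unfolded protein response (-0.18), hypoxia and glycolysis (-0.60), oxidative phosphorylation (-0.38), cholesterol synthesis (-0.58), lysosome (-0.15), ribosomal (-0.45) and housekeeping (-0.40) genes, as did Ndufa1 (-0.00733). After loess the ribosomal median was -0.00864, and with the mean over probes Aldh3a1 was -0.24. Without scaling, medians moved from above 0 for heme synthesis (-0.79), p53 (-0.86), heat shock (-0.57) and metallothionein (-0.36) genes. They also moved for megakaryocyte (-4.80), early neutrophil (-3.40), late neutrophil (-4.46), macrophage (-1.28), interferon (-1.74), dendritic (-1.60), B cell (-1.32), eosinophil (-4.84), stromal (-3.60), G1/S (-1.53), mitosis (-1.99), haematopoietic cytokine (-1.46) and immediate early (-1.80) genes. After loess they moved for G1/S (-0.77), mitosis (-1.16), oxidative phosphorylation (0.21), lysosome (0.35) and housekeeping (0.073) genes. With quantile normalization and with the authors' value table they moved for oxidative phosphorylation (0.32 and 0.32), lysosome (0.44 and 0.43), ribosomal (0.028 and 0.025) and housekeeping (0.037 and 0.036) genes. With normexp the stromal median was -1.84. Signal over background limits the dim genes, whose spot noise was larger (SD of a difference 0.071 against 0.036 for brighter probes).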

Other observations

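Families of genes that share a symbol stem also differed, in a screen of 228 families of at least 8 measured genes made after the data were seen. Cxcl chemokines had a median of -3.07 (7 of 8 at least 2-fold lower), Gimap GTPases of lymphocytes -2.61 (8 of 8), interferon-induced Gbp GTPases -2.33 (8 of 10) and Ccr chemokine receptors -1.77 (7 of 10). In the other direction, as scaled, Tmed cargo receptors of the secretory pathway had a median of 0.85 (2 of 9 at least 2-fold higher), Emc subunits of a membrane protein complex 0.81 (3 of 9), Ndufaf assembly factors of respiratory complex I 0.79 (3 of 8) and Alg enzymes of N-glycan synthesis 0.70 (3 of 12). The Gas and Klk stems had medians of 0.86 (1 of 8) and 0.75 (4 of 14). Removing the scaling lowers each value by 1.02, which takes all 6 medians below 0. By chance alone about 2.5% of the 228 families would lie in the outer 2.5% of matched random lists on each side, and 22 and 26 families did. Olfactory receptor genes, not expected in marrow, were among the 26, with a median of 0.64 at percentile 99.6. The higher families may thus hold background, which was not tested for them.

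On chromosome 12, 5 transcripts without a gene name, between 114496985 and 114544797 (mm9), differed by -9.16 to -7.35. The probe for Igh-VJ558, at -9.89, starts within this stretch at 114498348. These transcripts were chosen after their values were seen.

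Of the tests below, those of intensity on the lower cell type lists, of background in dim probes, of the 3 higher lists together by loess, and of glucocorticoid and cAMP responses were written before their results were seen. The tests of a single factor, of dilution, of culture differences, of spike-in yield and of percentiles per list were chosen after seeing related values.

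The lower medians of T and NK, mast cell, megakaryocyte, eosinophil and late neutrophil genes were weighed first. A single factor for the array is argued against, since the highest of these 5 medians lay -3.60 from the lysosome median, and so is a trend with brightness, since after loess the highest was -2.92. Equal dilution by another cell type would lower B cell genes alike. The list medians go against this for the lists other than T and NK, without excluding it. Their highest upper bound was -2.23, against a lower bound of -0.71 for B cells. The argument rests on B cell surface genes such as Cd79a, at -0.28, and Cd79b, at -0.50, named with their values known. The 11 brighter members of the B cell list had a median of -0.28. Other B cell genes were as low as the 4 lists. The antibody genes Jchain and Igh-VJ558 stood at -5.80 and -9.89, Vpreb3 at -4.34, and Igll1 was at least 11.2-fold lower. B cell genes thus disagreed with each other, and the intervals treat member genes as separate draws, so dilution is not excluded. For T and NK genes dilution stays open, since their upper bound of -0.76 lay within 0.19 of the B cell bound. That margin is the 95th percentile of the spot SD of a difference and was set after the values were known. T and NK members detected on the control array alone do not enter their bound. A difference between 2 cultures unrelated to the drug cannot be told apart from an effect of NYT with 1 array per group. An effect of NYT on which cells survived or matured may also account for the pattern and was not tested.

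The higher medians of lysosome, unfolded protein response and oxidative stress genes may reflect a bias with brightness. The test planned for this decided nothing, since the lowest loess median was 0.18 and 1 of 3 lay under the bound of 0.3. A second test was then chosen with the loess medians known, asking first of the 3 lists together and then of each part whether it stayed in the top 2.5% of matched random lists as scaled and after loess, and a looser bound tried for oxidative stress, which would have left that list undecided, was dropped. All 3 lists were already known to lie in the top 2.5% as scaled, so only the part after loess could fail. The lowest percentile of the lysosome and unfolded protein response lists, 99.99, was the lysosome value as scaled and thus decides nothing. After loess both lists stood at percentile 100, which argues against bias with brightness alone for these genes. For oxidative stress genes, at 95.5 after loess, such bias stays open. A larger share of a smaller mRNA yield was not decided, since spike-in scaling moves every gene by 1 constant, which fixes the outcome (highest of the 3 medians -0.31), and the spike-in slope on the NYT array was out of range.

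Background left in dim probes was a hypothesis for the 2-fold higher genes. Over 60% in the dimmer part was expected and at most 50% would have argued against it, and 54.7% lay there, which decides nothing, while 66.5% of the lower genes did. Olfactory receptor genes, not expected in marrow, had a median of 0.64 over 78 measured genes, so dim values above 0 may hold background. Normexp background correction gave a median of 0.76 for these genes (all genes 0.34). Its offset of 50 is added to both arrays before scaling, which raises dim genes on the dimmer NYT array. That value therefore decides nothing. The dimmer genes had a lower median than the brighter ones (0.20 against 0.35). The dimmer part was set by the mean of both arrays, so genes that were lower on the NYT array tend to fall in it. That comparison therefore does not count against background. With no filter on dim probes the median of all genes was 0.50. Background stays open.

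A shared hormone or second messenger response was a hypothesis for Dio2, Npy and Cdkn1c, tested on 2 lists that left out genes already seen. Glucocorticoid-induced genes had a median of -0.68 over 14 genes (2 higher, 6 lower, interval -1.76 to 0.81), at percentile 0 of matched random lists. Genes induced by cAMP had a median of -0.78 over 11 genes (0 higher, 4 lower, interval -1.39 to 0.43), at percentile 0.20. Per1 is in both lists, and members such as Il1r2 (-3.59) are also expressed by neutrophils, whose markers were lower. The glucocorticoid targets Tsc22d3 and Sgk1 were the 2 higher members, at 1.36 and 1.15, so a response in the cells that remained may be hidden.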
